A study of Mus musculus with 4 samples.

How the data were processed

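RNA was measured in 4 libraries of cells sorted as Fgf10-positive from the mouse submandibular gland, 2 from adults at postnatal day 60 and 2 from pups at postnatal day 7. Per the labels' protocols, RNA was isolated with a column kit and 1 ng of total RNA per library went into the SMART-Seq HT kit, a full-length cDNA method that amplifies by PCR and does not mark strand. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which for the pups may be technical. The adults differed in Y-linked RNA and so did not come from one source of RNA.

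The deposited values used here are raw read counts per Ensembl gene, one file per library. The submitters' processing notes name cutadapt 1.18 (an adapter trimmer), STAR 2.5.2a (a spliced aligner), HTSeq 0.11.0 (a read counter), R 3.5.1, DESeq2 1.20.0 and the genome build GRCm38. The options, the annotation release and the strand setting are not given in the sources used here. Each file ends with HTSeq's tallies of reads that had no feature, were ambiguous or were not uniquely aligned. Reads with no feature are called outside genes below. They may include reads in introns, since the counting options are not given. All the tallies together made up 32.9% and 32.3% of all reads tallied in the adults and 84.4% and 31.5% in pup replicates 1 and 2. They were left out of library sizes and tests. There were 2 tables of the whole series that were not used, because the names of their 8 value columns match no single sample.

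Each file held 53465 genes, of which 53360 matched a gene ID of the GENCODE vM21 annotation of GRCm38, the source of symbols, positions and exon lengths. Reads of near-identical genes may be split or dropped in such counts. Without strand, reads from overlapping or antisense genes cannot be told apart: 23.1% of the exon length of Mest and 26.1% of that of Pdgfa is shared with another gene. The list entries Muc10 and Gtl2 matched no gene symbol and were left out.

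Counts were analysed in R 4.3.3. The main test was the quasi-likelihood F test of edgeR 4.0.16 on the counts as deposited, with TMM factors, edgeR's filterByExpr (minimum count 10, minimum total 15), age as the only term and Benjamini-Hochberg adjusted p under 0.05. A positive log2 fold change means higher in adult. It tested 16320 genes at a common biological coefficient of variation of 0.895. CPM are TMM-scaled. Gene lists were tested with camera of limma 3.58.1 on edgeR's object, at a preset correlation of 0.01 and with adjustment over the 22 lists of at least 3 tested members. Camera compares a list with all other genes, so a list can have a negative median and an upward direction. Beside it stand camera with an estimated correlation and fry. Of the 22 lists, 9 were called higher and 7 lower in adult with the preset correlation, 0 with an estimated one, and 1 by fry. In all, 23 lists had been fixed, 5 of them as main lists (ionocyte markers, general epithelium, mesenchymal identity, extracellular matrix and V-ATPase subunits).

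The tests, lists, named genes and most alternatives were fixed before the data were examined. By that rule the text names 10 genes whatever their values, the called genes with the largest folds (10 per direction) and the largest differences in CPM (6 per direction), and per list up to 4 called members or, with fewer than 2 called, the 2 tested members of highest mean CPM. The fold part asked for at least 50 mean CPM in the higher age and for both libraries of one age above both of the other. As edgeR called 0 genes, the parts for called genes were empty; the same ranking was applied to the DESeq2 calls, and members called within their list alone and the 15 calls of the stricter filter were named, after the values were seen, except 1 gene that is not reported here.

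Alternatives were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, no filter beyond 1 count, a filter of 10 counts in every library of an age, DESeq2 1.42.0, limma-voom, an adjusted p of 0.01, edgeR's glmTreat against a fold of 2, the replicate number as a block, and each library left out in turn. Leaving out one library leaves a lone sample, assumed to vary like the other age. Chosen after seeing the data were a subtraction of the background of pup replicate 1 and the leave-one-out fits, for counts and lists, on the 16320 genes. When the filter is applied anew to 3 libraries with pup replicate 1 among them, 29829 to 30100 genes enter, and camera then compares lists with a different set of genes. The background was estimated from counts per kb of exon over olfactory receptor genes, multiplied by each gene's exon length, at 0.5 of that rate on X and Y. The median log2 fold change of all genes was -0.24 under TMM, and it shifted by -0.07, -0.18 and -0.38 under DESeq2 size factors, upper-quartile factors and library totals. Folds against an age with 0 counts use a floor of 3 counts over the group, and where the adults had 0 counts, those of pup replicate 1 were set to 0 as well. These floors, and the intervals of ratios and shares of genes with a count, cover counting error only, since PCR reads are not independent molecules. Intervals of list medians, of the ratio of autosome medians and of the reads expected outside genes come from 2000 bootstrap draws over genes. They leave out the spread between libraries and treat list members as independent, although the estimated correlation among respiratory chain members was 0.930.

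The fits were tested on simulated counts for this comparison, drawn from the real means, library sizes and dispersions, with 200 genes changed. Of 14969 simulated genes tested, edgeR called 0%, 22.0%, 40.0% and 86.0% of genes changed 4, 8, 32 and 100-fold with 6 false calls. DESeq2 called 20.0%, 56.0%, 56.0% and 92.0% with 152 false calls, and limma-voom 2.00%, 24.0%, 30.0% and 52.0% with 5. A list of 20 genes raised 4-fold was called by camera with the preset correlation and missed by camera with an estimated correlation and by fry, each with 0 false lists. These simulated list members varied independently of each other, which real list members need not do. All other simulated genes did so too. Neither the background of pup replicate 1 nor a difference in cell makeup between libraries of an age was simulated. The first fits to the real counts were made before this simulation, and the largest simulated fold was lowered to 100 after a first run; no setting of the tests was changed in between.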

Results

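Messenger RNA was sequenced from cells sorted as Fgf10-positive out of the mouse submandibular gland, a salivary gland whose acini and ducts are epithelial and lie in a mesenchymal stroma. The mice carried a tamoxifen-inducible Cre under Fgf10 control and a Tomato reporter, so that cells expressing Fgf10 at the time of tamoxifen became fluorescent. Adults were taken at postnatal day 60 after tamoxifen on days 57 and 58, and pups at postnatal day 7 after tamoxifen on days 4 and 5, each at 0.1 mg per g of body weight. There were 2 libraries per age. Counts over genes came to 13791730 in adult replicate 1, 16585518 in adult replicate 2, 7289792 in pup replicate 1 and 21490686 in pup replicate 2.

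The libraries differed in makeup as well as in depth. Between 16805 and 19764 genes had a count in 3 of the libraries, and 44734 in pup replicate 1. Reads that HTSeq assigned to no feature, here called outside genes, made up 76.7% of all reads tallied in that library. The shares were 9.70%, 9.90% and 10.6% in adult replicate 1, adult replicate 2 and pup replicate 2. Olfactory receptor genes, a family used in the nose, had a count for 96.5% of 1134 members in pup replicate 1 and for 1.59%, 7.67% and 3.17% in the others. The expected background over genes at that rate was 24.1% of the gene counts of pup replicate 1. Pearson's correlation of log2 CPM across genes, which are not independent replicates, was 0.825 between the adults and 0.784 between the pups, and 0.625 to 0.773 between ages. Counts of the adult pair differed far beyond sampling noise (chi-square per degree of freedom 222), as did those of the pup pair (155), and each library was counted once. That test covers counting error only and cannot tell repeat libraries of one RNA from separate samples. Mitochondria-encoded genes took 6.76% and 7.30% of counts in the adults and 1.07% and 1.86% in the pups.

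**Figure D1:**
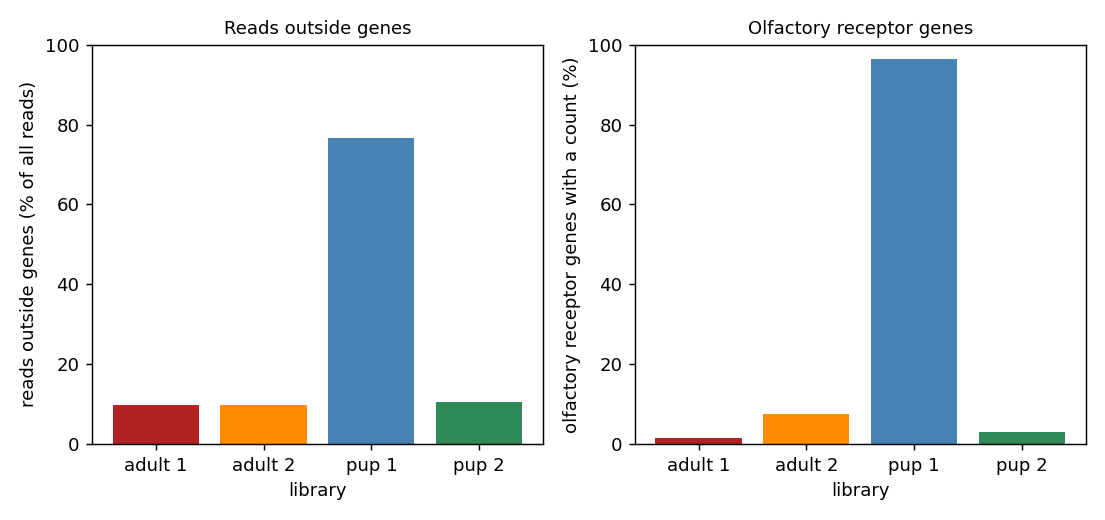
Left, share of reads outside genes (no feature, which may include introns), as a percent of all reads tallied. Right, share of olfactory receptor genes with at least 1 count, one bar per library. Pup replicate 1 stands at 76.7% and 96.5%, and each other library lies at or below 10.6% and 7.67%.

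RNA of Y-linked genes separated the adults. Ddx3y had 0 counts in adult replicate 1 and 556, 491 and 1324 counts in adult replicate 2, pup replicate 1 and pup replicate 2. A count of 0 excludes only levels above the floor of 3 counts. Eif2s3y gave 0, 398, 183 and 312 counts, Kdm5d 0, 132, 101 and 92, and Uty 1, 140, 131 and 84, in the same order. For Kdm5d and Uty the expected background in pup replicate 1 was 106 and 68.5 counts. Xist, which is transcribed from the inactive X chromosome, had 795, 258, 238 and 574 counts, with 126 expected from background in pup replicate 1. Adult replicate 2 and pup replicate 2 thus held both Xist and Y-linked RNA, so Y-linked RNA does not show that either came from males alone. The labels give no sex, and the expected background counts take X and Y at 0.5 of the rate, as for male DNA.

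The comparison of adult with pup asks how the transcriptome of Fgf10-positive cells differs between the ages. Fgf10 itself (ENSMUSG00000021732, chromosome 13, 118669791 to 118792115 in GRCm38), a secreted growth factor, stood at 195 and 40.3 CPM in the adults and 27.3 and 24.1 CPM in the pups. Its log2 fold change of adult over pup was 2.20 ± 0.79 (SE, 2 libraries per age) and did not pass (edgeR adjusted p = 0.284, DESeq2 adjusted p = 0.107). With the filter applied anew, the Fgf10 value was 0.79 without adult replicate 1 and 3.01 without adult replicate 2. Foxi1 (ENSMUSG00000047861, chromosome 11, 34204338 to 34208089), the transcription factor that directs ionocyte fate, averaged 997 ± 288 CPM (SD, n = 2) in the adults and 5.97 ± 2.48 CPM in the pups, a log2 fold change of 7.37 ± 0.98 (SE). Ascl3, a transcription factor of salivary duct cells, averaged 488 ± 256 CPM against 3.75 ± 0.56 CPM (log2 fold change 7.01 ± 0.84), and Cftr, the chloride channel mutated in cystic fibrosis, 158 ± 102 CPM against 11.2 ± 9.09 CPM (3.83 ± 0.88). Of the 39 Foxi1 counts in pup replicate 1, 33.0 were expected from background, as were 109 of the 163 Cftr counts. Without pup replicate 1 and with the filter applied anew, the log2 fold change of Cftr was 5.05. The background rate is an average and did not hold gene by gene: Hspb7 had 0 counts in pup replicate 1 with 38.7 expected, Bsnd 10 with 38.5 and Rab17 7 with 27.9. None of these genes passed edgeR's adjusted threshold, with adjusted p of 0.164 for Foxi1, 0.161 for Ascl3 and 0.232 for Cftr, whereas DESeq2 gave 1.22e-39, 1.87e-27 and 0.000990.

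**Figure D2:**
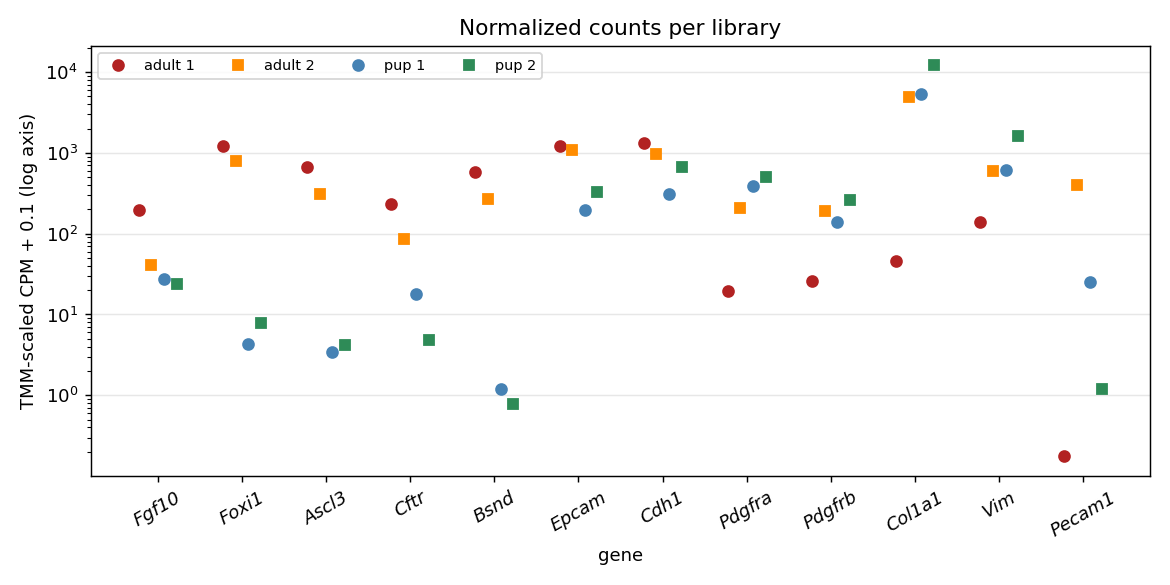
TMM-scaled CPM plus 0.1 on a log axis for 12 genes, one point per library. Foxi1, Ascl3, Cftr and Bsnd lie higher in both adults than in both pups, and Pdgfra, Pdgfrb, Col1a1 and Pecam1 lie far lower in adult replicate 1 than in adult replicate 2.

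Over 16320 genes tested, edgeR's quasi-likelihood test called 0 genes higher in adult and 0 higher in pup at an adjusted p of 0.05, the smallest adjusted p being 0.141. At an unadjusted p under 0.05 the numbers were 978 higher in adult and 1385 higher in pup by edgeR, and 1220 and 1001 by limma-voom. DESeq2 called 597 and 848 genes, and limma-voom 0 and 0 (smallest adjusted p 0.0613). In data simulated from these libraries, edgeR called 86.0% of genes changed 100-fold and 40.0% of those changed 32-fold with 6 false calls. DESeq2 made 152 false calls beside 112 right ones there. The simulated genes varied independently, with no background particular to pup replicate 1 and no difference in cell makeup between libraries of an age. Those shares need not hold for the real libraries, where edgeR did not call Foxi1 at a log2 fold change of 7.37. Both libraries of one age lay above both of the other for 7971 genes (48.8%, where chance gives 33.3%), of which 3553 were higher in adult. As genes are not independent, the spread of that share is unknown, and the excess over 33.3% was not tested. On the same 16320 genes edgeR called 229 higher in adult and 161 higher in pup without adult replicate 1, 247 and 733 without adult replicate 2, and 0 and 0 without either pup library. With the filter applied anew, which took in 30100 and 29951 genes, the numbers were 151 and 64 without adult replicate 1 and 156 and 368 without adult replicate 2. All values below for lists without a library are on the 16320 genes unless said otherwise, a choice made after seeing the data. With only 2 libraries per age, an exact two-sided permutation test of a single gene cannot go below 0.333.

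By edgeR with all 4 libraries, the filter decided whether any gene passed. Asking for 10 counts in every library of at least 1 age left 15186 genes, of which edgeR called 13 higher in adult and 2 higher in pup, and DESeq2 called all 15 as well. These 15 were singled out after their values were seen. Among those higher in adult were Hspb7, a small heat shock protein, Slc44a4, Asgr1, Bsnd, an accessory subunit of chloride channels, Rab17, Mal, Bspry, Bcl2l14, Rtp4, Ascl3, Prr15l and the predicted gene Gm12888. Zim1, an imprinted zinc finger gene, and Dlk1, an imprinted inhibitor of adipogenesis, were higher in pup. Hspb7 had 0 counts in the pups and was at least 1180-fold higher in adult, and Zim1 had 0 counts in the adults and was at least 629-fold lower there, each against a floor of 3 counts over the group. For Zim1 every count of pup replicate 1 was taken as background, as in the other bounds on genes with 0 counts in the adults. Bsnd averaged 423 ± 224 CPM (SD) in the adults against 0.883 ± 0.282 CPM in the pups, and Dlk1 1.72 ± 1.13 CPM against 375 ± 205 CPM.

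Ranking the genes that DESeq2 called by the rule fixed for called genes gave, by fold, Hspb7, Mc4r, Bsnd, Klk1b26, Mucl2, Esp4, Klk1b9, Scgb2b26, Scgb2b27 and Foxi1 in adult. The corresponding pup genes were Zim1, Dcpp2, H19, Igdcc4, Dlk1, Col26a1, Cnmd, Dcpp1, Adam12 and Col6a6. By difference in CPM it gave Mucl2, Scgb1b27, Klk1, Anxa1, Fxyd2 and Ifi27l2a in adult, and Col4a1, Ccn1, Itm2a, Col4a2, Krt14 and Thbs1 in pup. Values were often carried by 1 library: Mucl2, a mucin-like salivary protein, stood at 392 and 37832 CPM in the adults, and Scgb1b27, a secretoglobin, at 81.7 and 13133 CPM. Mc4r, with 3 counts in the pups, gave a ratio of 847 (95% counting interval 289 to 4108, which covers counting error only). Klk1b26, Klk1b9, Dcpp1, Dcpp2, Mucl2, Scgb1b27, Scgb2b26 and Scgb2b27 belong to families of near-identical copies, so their counts are uncertain.

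Ionocyte markers rose in adult as a list. Of 22 members 21 were tested, 20 had a positive log2 fold change, and the median was 5.49. Camera gave an adjusted p of 8.68e-37 with its preset correlation, but 0.238 as adjusted p with an estimated correlation. By edgeR no member was called over all genes, and 17 were called higher and 0 lower adjusted over the list alone. DESeq2 called 17 higher over all genes. Beside Foxi1 and Ascl3 these included Bsnd, with a log2 fold change of 8.92 ± 0.91 (SE). Of the highest members, Tfcp2l1, a transcription factor of transporting epithelia, stood at 1870 and 2078 CPM in the adults against 104 and 171 CPM in the pups, and Hepacam2 at 1603 and 623 against 17.3 and 2.10 CPM. In adult replicate 1 the list's median was 388 CPM, in adult replicate 2 it was 199 CPM. The median log2 fold change was 4.51 without adult replicate 1 and 6.66 without pup replicate 1.

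Subunits of the V-ATPase, the proton pump of acid-secreting cells and lysosomes, rose as a list in adult, with 22 of 23 tested members positive and a median log2 fold change of 1.52 (camera adjusted p = 1.79e-12, adjusted p = 0.255 with an estimated correlation). By edgeR 0 were called over all genes, and adjusted over the list alone 6 higher and 0 lower, while DESeq2 called 8 higher. Among them were Atp6v0d2, at 1397 and 591 against 12.3 and 8.46 CPM, Atp6v1b1 (log2 fold change 4.46 ± 0.72, SE), Atp6v1g3 (4.67 ± 0.90) and Atp6v1d (2.56 ± 0.63), the first 3 of which, with Atp6v1c2 and Atp6v0a4, are also on the ionocyte list. Atp6ap2, another of the most abundant members, had a log2 fold change of 2.40 ± 0.84.

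The list for ion and water transport of secretory epithelium rose as well, 25 of 28 tested members being positive with a median of 3.04 (camera adjusted p = 1.08e-17, adjusted p = 0.220 with an estimated correlation). It was called by fry, a test of whether the members move on balance one way, at an adjusted p of 0.0426. By edgeR 11 members were higher and 0 lower adjusted over the list alone, and 0 were called over all genes, where DESeq2 called 13 higher. Examples were Scnn1a, a subunit of the epithelial sodium channel, at 4.20 ± 0.55 (SE), Slc4a11 at 5.96 ± 0.99 and Slc12a2, the sodium-potassium-chloride cotransporter, at 5.77 ± 1.40. Fxyd2, a regulator of the sodium pump, averaged 4936 ± 1983 CPM in the adults and 73.4 ± 46.6 CPM in the pups. Of 36 members listed, 14 stand on another list too. The median was 1.76 without adult replicate 2 and 3.93 without pup replicate 1. With the filter applied anew, 35 members entered and the median without adult replicate 2 was 0.12.

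General epithelial genes rose in adult, with 22 of 24 positive and a median of 2.12 (camera adjusted p = 3.17e-15, adjusted p = 0.238 with an estimated correlation). By edgeR 0 were called over all genes (15 higher by DESeq2), and adjusted over the list alone 11 were higher and 0 lower, among them Rab25, Spint1, Elf3 and St14 at 4.30 ± 0.71, 3.57 ± 0.62, 3.68 ± 0.67 and 3.80 ± 0.76 (SE). Epcam, an adhesion molecule of epithelial cells, averaged 1155 ± 111 CPM (SD) in adult and 262 ± 92.8 CPM in pup, and Cdh1, the gene for E-cadherin, 1151 ± 247 against 488 ± 254 CPM. The keratin genes Krt18 and Krt8 did not pass by edgeR, with DESeq2 adjusted p of 0.000683 and 0.171. Krt18 had a log2 fold change of 2.67 ± 1.34, and Krt8 stood at 1138 and 3216 CPM in the adults and 385 and 1040 CPM in the pups. Salivary duct markers rose too, with 14 of 15 positive and a median of 1.98 (camera adjusted p = 4.97e-08, adjusted p = 0.238 with an estimated correlation). By edgeR they had 4 members higher and 0 lower adjusted over the list alone (Scnn1a, Scnn1b, Fxyd2 and Ehf) and 0 called over all genes, where DESeq2 called 5 higher. The highest members were Fxyd2 and Wfdc18, the latter at 97.0 and 6416 CPM in the adults. Without adult replicate 2 the duct median was 1.32.

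Mesenchymal identity genes fell in adult by camera, with 20 of 25 negative and a median of -1.62 (adjusted p = 0.000108, but adjusted p = 0.591 with an estimated correlation). By edgeR no member was called, over all genes or adjusted over the list alone, and DESeq2 called 1 higher and 4 lower. Pdgfra, a receptor of fibroblasts, stood at 19.4 and 210 CPM in the adults and 387 and 508 CPM in the pups, and Pdgfrb at 26.1 and 190 against 140 and 263 CPM. Vim, an intermediate filament gene, stood at 139 and 602 CPM against 610 and 1608 CPM. The call ended without adult replicate 1 (adjusted p = 0.0560, median -0.91) and without pup replicate 2 (adjusted p = 0.0502, median -1.11), and the median was -4.17 without adult replicate 2. Extracellular matrix genes fell in adult with 40 of 41 negative and a median of -1.80 (camera adjusted p = 2.36e-10, adjusted p = 0.564 with an estimated correlation), and edgeR called 0 members by either adjustment, DESeq2 6 lower. Col1a1, Col3a1 and Col1a2, the main fibrillar collagens, had log2 fold changes of -1.82 ± 2.39, -1.99 ± 2.84 and -1.80 ± 2.39 (SE). Col1a1 stood at 46.3 and 4900 CPM in the adults, so that on the log2 scale the spread within the age exceeded the difference between ages. The matrix median was -1.04 without adult replicate 1, -0.98 without pup replicate 2 and -5.03 without adult replicate 2, the call holding in each. With the filter applied anew, the fit without pup replicate 2 gave adjusted p of 0.162 for the matrix and 0.312 for the mesenchymal list, with the direction relative to other genes turned. The fit without adult replicate 1 then gave 0.575 for the mesenchymal list.

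**Figure D3:**
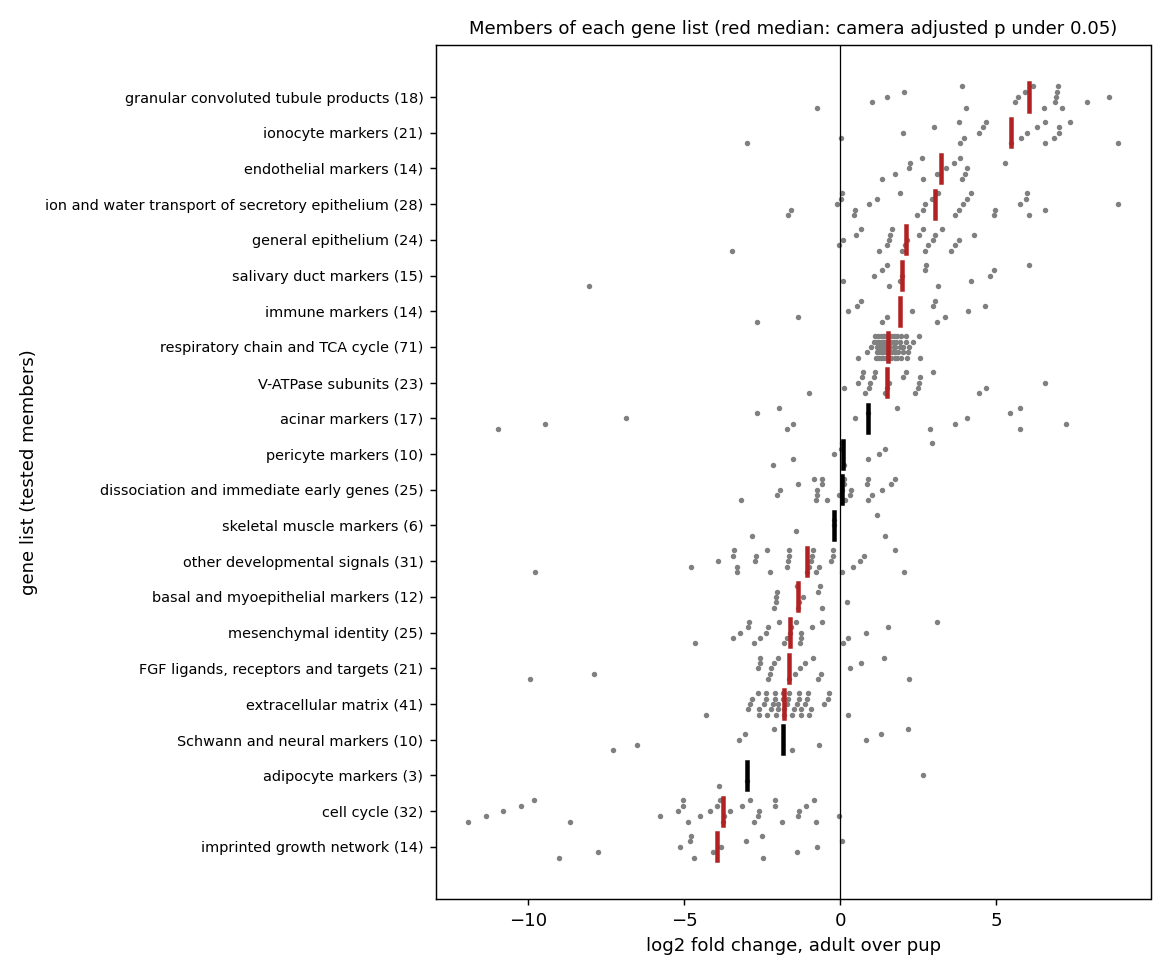
Log2 fold change of adult over pup for each tested member (points) of 22 gene lists, with the list's median as a bar, red where camera's adjusted p with the preset correlation lay under 0.05. The ionocyte median is 5.49 and the cell cycle median -3.74. Points beyond about 10 in size have 0 counts in one age and depend on the prior count.

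Genes of cell division fell in adult. All 32 tested members of the cell cycle list were negative, with a median of -3.74 (camera adjusted p = 8.80e-17, adjusted p = 0.238 with an estimated correlation), and by edgeR 13 were lower and 0 higher adjusted over the list alone. Cenpf and Kif11, with 0 counts in the adults, were at least 167-fold and 76.2-fold lower there. Background was expected to give 216 of the 306 Cenpf counts and 104 of the 285 Kif11 counts in pup replicate 1. Mki67, a proliferation marker, had 1 count in the adults, 991 in pup replicate 2 and 286 in pup replicate 1, 141 of the last expected from background. Top2a stood at 5.90 and 2.23 CPM against 63.0 and 62.2 CPM, and the most abundant members, Mcm6 and Pcna, had log2 fold changes of -1.33 ± 0.65 and -0.77 ± 0.52. The imprinted growth network fell, with 13 of 14 tested members negative and a median of -3.94 (camera adjusted p = 6.49e-13, adjusted p = 0.238 with an estimated correlation). By edgeR 9 were lower and 0 higher adjusted over the list alone, led by Dlk1, Rian, Peg3 and Mest at -7.76 ± 0.97, -4.08 ± 0.77, -4.77 ± 0.96 and -4.82 ± 1.07 (SE). H19, a noncoding RNA next to Igf2, stood at 4.98 and 0 CPM in the adults and 527 and 2065 CPM in the pups. By edgeR 0 members of either list were called over all genes, while DESeq2 called 15 and 10 lower. The calls of both lists held without each library, the imprinted median being -3.32 without adult replicate 1 and -5.50 without adult replicate 2. With the filter applied anew, both calls ended without pup replicate 2 (adjusted p = 0.938).

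Products of the granular convoluted tubule, the male-biased duct segment that secretes kallikreins and growth factors, rose in adult with 17 of 18 positive and a median of 6.06 (camera adjusted p = 3.30e-17, adjusted p = 0.272 with an estimated correlation). By edgeR 13 were higher and 0 lower adjusted over the list alone and 0 were called over all genes, where DESeq2 called 10 higher. Crisp3 averaged 1505 ± 434 CPM in adult against 12.4 ± 6.53 CPM in pup, Klk1 stood at 3532 and 7759 against 37.9 and 190 CPM, and Klk1b5 had a log2 fold change of 6.98 ± 1.09. Adult replicate 2, the adult library with Y-linked RNA, exceeded adult replicate 1 by a median log2 ratio of 2.70 over the list. Its median log2 fold change was 3.30 without adult replicate 2, 6.92 without adult replicate 1 and 7.82 without pup replicate 1. Acinar markers did not pass (limma's camera, adjusted p = 0.778). Their median was 0.89 while camera's direction was down, 10 of 17 being positive. By edgeR Slc12a2 was higher and Dcpp1, Dcpp2 and Dcpp3 lower adjusted over the list alone, Dcpp3 at least 151-fold. DESeq2 called 2 acinar members higher and 4 lower. Pip, a secreted protein of acini, stood at 62.0 and 10397 CPM in the adults. The acinar list's direction turned up without adult replicate 1 (adjusted p = 1.70e-05), and the list was lower without adult replicate 2 (0.000967).

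FGF ligands, receptors and targets fell, with 17 of 21 negative and a median of -1.63 (camera adjusted p = 0.000229, adjusted p = 0.255 with an estimated correlation). By edgeR Fgfr2 was the single member lower adjusted over the list alone (-2.56 ± 0.48, SE) and 0 were higher. Fgfr1 stood at 69.9 and 98.2 against 406 and 436 CPM, and Dusp6, a target of the pathway, at 171 and 219 against 375 and 699 CPM. Other developmental signals fell, with 25 of 31 negative and a median of -1.08 (camera adjusted p = 0.000108, adjusted p = 0.439 with an estimated correlation). Adjusted over that list alone edgeR called 0, the highest members being Igf1 (-1.08 ± 1.52) and Pdgfa (-0.78 ± 0.64). By edgeR 0 members of these lists were called over all genes, while DESeq2 called 7 FGF members lower, and 1 higher and 7 lower among the other signals. Both calls held without each library, with medians of -2.42 and -3.17 without adult replicate 2 and -1.35 and -0.73 without adult replicate 1. With the filter applied anew they ended without adult replicate 1 (adjusted p = 0.0604 and 0.624) and without pup replicate 2 (0.959 and 0.372, with the direction relative to other genes turned).

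Transcripts of the respiratory chain and TCA cycle rose in adult, with all 71 members positive and a median of 1.53 (camera adjusted p = 7.95e-23, adjusted p = 0.452 with an estimated correlation). By edgeR no member was called by either adjustment, and DESeq2 called 16 higher. Cox4i1 and Cox8a, subunits of cytochrome c oxidase, had log2 fold changes of 1.25 ± 0.94 (SE) and 2.12, Cox8a standing at 1474 and 824 against 112 and 418 CPM. The list's median CPM was 378 and 235 in the adults and 58.1 and 146 in pup replicates 1 and 2. Without pup replicate 1, the library with the background, the median was 1.01 (camera adjusted p = 9.19e-12), and without pup replicate 2 it was 2.45. The call held in both, and RNA from the mitochondrial genome was likewise a larger share of counts in the adults.

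Markers of cells that a sort of Fgf10-positive cells could also hold differed between the adult libraries. Endothelial markers rose by camera, with 14 of 14 positive and a median of 3.25 (adjusted p = 0.0299, adjusted p = 0.628 with an estimated correlation), and edgeR called 0 by either adjustment, DESeq2 2 higher. Plvap stood at 1.38 and 1160 CPM in the adults and 8.12 and 21.2 CPM in the pups, Vwf at 260 and 506 against 43.4 and 3.84 CPM. The list's median was 0 CPM in adult replicate 1, 9.85 CPM in pup replicate 1 with its background, and 1.08 CPM in pup replicate 2. The size of a median fold against adult replicate 1 alone thus depends on the prior count. Without adult replicate 2 camera's direction turned, with a median of -7.98 and an adjusted p of 0.0643. The call also ended without pup replicate 1 (0.0540, median 6.00) and without pup replicate 2 (0.505), though it held in the latter with the filter applied anew (0.0233). Immune markers rose, with 12 of 14 positive and a median of 1.91 (camera adjusted p = 0.000128, adjusted p = 0.272 with an estimated correlation). The 3 members that edgeR called higher adjusted over the list alone, H2-Ab1, H2-Aa and Cd74, all serve antigen presentation by MHC class II, and 0 were lower. Over all genes edgeR called 0 and DESeq2 3 higher. The immune call ended without pup replicate 2 (adjusted p = 0.0726, median 1.34), and the median was 3.54 without pup replicate 1. With the filter applied anew, 18 members entered, and without pup replicate 2 the call held (0.0292) at a median of 0.45. Basal and myoepithelial markers fell, with 11 of 12 negative and a median of -1.35 (camera adjusted p = 0.00987, adjusted p = 0.595 with an estimated correlation), and edgeR called 0 members, DESeq2 2 lower. The call ended without adult replicate 2 (0.361, median -0.92) and without pup replicate 2 (0.589, median -0.41). In the latter its direction turned with the filter applied anew (0.172). Krt14 stood at 736 and 253 against 1257 and 2849 CPM, Acta2 at 2907 and 1197 against 2406 and 8235 CPM.

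The remaining lists did not pass with all 4 libraries. Schwann and neural markers had a median of -1.84 (limma's camera, adjusted p = 0.214), with Erbb3 higher adjusted over the list alone (2.19 ± 0.49, SE) and Sox10 at -1.56 ± 0.69. Pericyte markers had a median of 0.11 (0.250), with Kcnj8 higher adjusted over the list alone (2.95 ± 0.58) and Rgs5 at -0.19 ± 0.98. Adipocyte markers, 3 of them tested, had a median of -2.99 (0.214), Lpl at -3.89 ± 1.26 and Fabp4 at 2.65 ± 1.56. Skeletal muscle markers had a median of -0.21 (0.563), with Des at 1.45 ± 0.71 and Myh1 at -2.81 ± 3.13. Dissociation and immediate early genes had a median of 0.05 (0.952), Fos at 0.85 ± 1.86 and Egr1 at -0.42 ± 1.40, and the direction turned with the scaling. Without a filter pericyte markers (0.00280) and dissociation genes (0.00427) were called higher in adult. Both were also called higher without pup replicate 2 (0.00175 and 2.28e-06), and pericyte markers without adult replicate 1 (0.00597), when the filter was applied anew, but not on the 16320 genes. Adipocyte markers were called lower without adult replicate 2 (0.0362). Of 8 erythroid markers only Alas2 was tested (-0.27 ± 2.41). These values in parentheses are camera's adjusted p with the preset correlation or log2 fold changes with SE.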

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

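Of the tests in this part, those of reads outside genes against the olfactory receptor rate, of the adult pair and of the respiratory chain were chosen only after the result was seen, and the bound for background as the cause of the respiratory chain difference was moved from 1 to 0 after its value was known.

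Reads outside genes, the no-feature tally that the comparison of ages does not use, were present in every library. They were 9.70% of all reads tallied in adult replicate 1, 9.90% in adult replicate 2, 76.7% in pup replicate 1 and 10.6% in pup replicate 2. No library without RNA was analysed here as a control, so the shares were not tested against a control.

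Pup replicate 1 had counts over genes with no count in the other libraries: 89.4% of 4959 such protein-coding genes had at least 1, at a median of 10.4 counts per kb. Unspliced RNA of expressed genes as the whole source is argued against by olfactory receptor genes, of which 96.5% had a count (95% interval 95.2 to 97.5). Genomic DNA may be the source: the olfactory receptor rate spread over the whole annotated chromosomes gives 1.01 times the reads outside genes (0.955 to 1.07). That length includes exons and introns alike, while the tally may include reads in introns. Evenness along the genome left this open, since the highest autosome median of counts per kb was 2.04 times the lowest (1.84 to 2.89, around the bound of 2 set in advance), while X stood at 0.471 of the autosome median. No biological explanation was tested.

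The adult libraries differed from each other in markers of other cells, adult replicate 2 exceeding adult replicate 1 by a median log2 ratio of 4.02 over matrix genes, 6.28 over endothelial markers and 2.71 over acinar markers. A lower share of ionocytes alone, which would raise all other markers alike, is argued against by basal and myoepithelial markers, at -1.02 (-1.49 to -0.54). Members higher in adult replicate 2 were 41 of 41 for matrix, 14 of 14 for endothelial and 15 of 17 for acinar markers. RNA of matrix and endothelial genes was thus more abundant there throughout both lists. Other cell types sorted with adult replicate 2 may account for the difference, and the sort for the reporter would have to have let them through. The test asked for all 3 lists alike, and the acinar median, 2.71, had an interval of 1.09 to 7.09, too wide to decide. Kallikreins and other granular tubule products were higher in adult replicate 2, the adult library with Y-linked RNA, by 2.70 (2.28 to 3.16). With 1 adult library with Y-linked RNA and 1 without, sex of the animals was not tested and stays open beside other cells and differences between animals.

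Transcripts of the nuclear-encoded respiratory chain were higher in adult by a median log2 fold change of 1.53 (1.48 to 1.63). Background in pup replicate 1 as the whole cause is argued against by the median without that library and with the filter applied anew, 1.01 (0.93 to 1.08), and by 1.42 after subtracting the background. The interval of 0.93 to 1.08 includes 1, the bound first set, so under that bound the test would have left this open. The fall from 1.53 to 1.01 leaves part of the size open. Age, a different makeup of cell types at each age, and damage to the sorted cells remain untested.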

How the results depend on the processing

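The fits with pup replicate 1 corrected for background, and the leave-one-out fits on the 16320 genes, were chosen after seeing the data. Numbers of calls were 0 higher in adult and 0 higher in pup under all 3 other scalings, limma-voom, the stricter adjusted p, glmTreat and the background correction. With 0 calls in the main fit, the stricter adjusted p and glmTreat could give no other number. Calls came to 284 and 231 with no filter, 13 and 2 with 10 counts in every library of an age, and 597 and 848 with DESeq2. Of the 515 calls without a filter, 444 lay among the 16320 genes that pass edgeR's own filter and 372 were DESeq2 calls. Leaving out one library gave 0 to 247 higher in adult and 0 to 733 higher in pup, with 0 in both directions when either pup library was left out and calls when either adult library was. The 151 and 64 calls without adult replicate 1 and the 156 and 368 without adult replicate 2, with the filter applied anew, shared 125 genes. A leave-one-out fit takes its spread from the age that keeps both libraries: the pups without an adult library, the adults without a pup library. Whether this accounts for the pattern of calls was not tested. With the replicate number as a replicate block the numbers were 0 and 0. Across genes, the difference between the adult replicates did not go with that between the pup replicates (correlation -0.0982). Background in pup replicate 1 and markers of other cells in adult replicate 2 could hide a shared factor, so pairing was not excluded. Of list calls, the block ended that of endothelial markers (camera adjusted p = 0.192).

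Camera with an estimated correlation ended the call of each list called with the preset one: the adjusted p was 0.238 for ionocyte markers and general epithelium, 0.255 for V-ATPase subunits, 0.591 for mesenchymal identity and 0.564 for the matrix. Fry gave 0.0972 for the first 3 and 0.376 for the last 2. For ion and water transport the estimated correlation was -0.0237, below the preset 0.01, and the call still ended (camera adjusted p = 0.220). Correlation among members thus does not account for that loss. In the simulation, camera with an estimated correlation and fry both missed a list of independent members raised 4-fold. A call lost with either therefore does not show that a list was unchanged. Dissociation genes, which were not called, turned direction with fry (0.839), DESeq2 size factors (0.960), library totals (0.499) and the background correction (0.198). Without a filter acinar markers turned up (0.0262), Schwann markers turned (0.990), and pericyte (0.00280) and dissociation genes (0.00427) were newly called. Pericyte markers were also called without adult replicate 1 (0.00597) and without pup replicate 2 (0.00175) with the filter applied anew.

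Leaving out one library, on the 16320 genes or with the filter applied anew, camera's adjusted p ran from 7.62e-11 to 0.726 for acinar, 0.0277 to 0.785 for adipocyte, 3.85e-05 to 0.589 for basal and myoepithelial, 2.28e-06 to 0.984 for dissociation, 2.03e-53 to 0.505 for endothelial, 3.13e-51 to 0.162 for matrix, 0.000204 to 0.959 for FGF, 3.72e-13 to 0.575 for mesenchymal, 1.02e-10 to 0.624 for other developmental signals, 0.115 to 0.938 for Schwann and 0.160 to 0.958 for skeletal muscle genes, each turning direction at least once. The main lists for ionocytes, epithelium and the V-ATPase kept direction and call in all such fits. Without pup replicate 2 camera's direction turned for 8 lists with the filter applied anew, which took in 29829 genes, and for 1 list (skeletal muscle) on the 16320 genes.

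Under another scaling or tool, or without a filter, none of 108 named genes turned direction, nor did any of the 107 tested at 10 counts in every library of an age. Leaving out one library, the log2 fold change changed sign for Acta2 (-2.10 to 0.0406), Alas2 (-8.27 to 0.81), Egr1 (-0.64 to 0.12), Fabp4 (-1.37 to 4.42), Myh1 (-9.63 to 7.11), Pcna (-1.17 to 0.0590), Pdgfa (-1.34 to 0.40), Pdgfrb (-2.89 to 0.000837), Pip (-0.58 to 7.08), Plvap (-3.36 to 6.43), Rgs5 (-1.67 to 1.73) and Wfdc18 (-0.24 to 7.30). Alas2 was also positive (0.29) after the background correction. Passing the adjusted threshold were 82 named genes with DESeq2, 61 without a filter and 15 at 10 counts. Depth limits pup replicate 1 most, where 24.1% of its 7289792 gene counts were expected from background.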

Other observations

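The interferon list in this part was chosen after its genes were seen to be high; the test against immune markers was fixed before its result was seen.

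Genes induced by interferon, the antiviral signal, stood higher in both adults than in both pups for 24 of 28 genes. Rtp4 stood at 252 and 187 CPM in the adults and 7.03 and 7.25 CPM in the pups, Ifit1 at 98.9 and 117 against 6.17 and 2.63 CPM, Isg15, a ubiquitin-like protein, at 74.9 and 80.2 against 0.974 and 4.10 CPM, and Irf7, a transcription factor of the response, at 387 and 256 against 17.4 and 7.30 CPM. Ifi27l2a was the most abundant, at 6190 and 2607 against 15.6 and 44.4 CPM. B2m, the light chain of MHC class I, stood at 1608 and 2097 against 183 and 490 CPM. Mx1 and Oas2 had negative log2 fold changes of -1.75 ± 2.59 and -1.94 ± 2.94 (SE). Both had 0 counts in pup replicate 2, so these signs rest on pup replicate 1. There Mx1 had 67 counts with 52.9 expected from background, and Oas2 had 34 with 62.3 expected. Without pup replicate 1 and with the filter applied anew, all 27 genes tested were higher in adult. Over all genes edgeR called 0 of the 28 and DESeq2 19. The median log2 fold change was 3.01, camera gave p = 1.69e-28 with the preset correlation and p = 0.00758 with an estimated correlation, and as the list was picked on these libraries neither is independent evidence. Leaving out one library, with the filter applied anew, gave medians from 2.83 to 3.59, over 27 genes without pup replicate 1 and 28 otherwise.

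As a hypothesis, the sorted adult cells may carry a stronger interferon response than the pup cells. Immune cells in the adult sorts are the other candidate source: the immune list without its MHC class II genes (11 tested) had a median of 1.33, below the interferon list by 1.68, with an interval from -0.12 to 2.91 that includes 0, so the test left this open. That gap came from the fit with pup replicate 1 and its background. Without pup replicate 1 and with the filter applied anew, the whole immune list, MHC class II genes included, had a median of 3.54. The interferon list then had a median of 3.59. The gap without the MHC class II genes was not computed for that fit. Age, housing and sex of the animals remain untested, and no gene of the interferon list stands on a list fixed in advance.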
